A study of Mus musculus with 2 samples.

How the data were processed

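RNA was sequenced from 2 libraries, 1 labelled Control and 1 labelled TRPM2-KD, both from the warm condition. Per the labels, plasmids carrying a Trpm2 knockdown or a control construct were electroporated in utero into the cortex of ICR mouse embryos at embryonic day 13, and GFP-positive neural progenitors were sorted at embryonic day 15. ICR is an outbred stock. The column header of the TRPM2-KD library names TRPM2-sh1. With no other knockdown construct in the data, effects of this construct cannot be told apart from those of lower Trpm2. How many embryos went into each library, the temperature and its duration are not given in the sources used here.

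The authors deposited 1 table with a line per gene. Per the file headers it holds a read count and an RPKM value (reads scaled by gene length and by the library total) for each library. The deposited counts are whole reads, not normalised. They sum to 26209192 in Control and 20791236 in TRPM2-KD over 16103 genes, and every listed gene has a CPM of at least 1.01 in 1 of the libraries or both, which is the smallest such value in the table. The deposited RPKM values equal the counts times a constant per gene, with the same ratio of 1.26 between the libraries for every gene with over 50 reads in both, so RPKM scales each library to its total. The table also gives the authors' log2 fold change, with a p-value and an adjusted p-value for each gene, per the file headers. The tool behind that comparison, and how its spread was set with 1 library per group, are not given in the sources used here. Per the submitters' processing notes, Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.0 and the mouse build mm9 were used, with no role or order stated. The annotation release, the treatment of strand and the treatment of reads that match several places are not given there. No column of another sample was found in the table. In the table, 23 gene symbols had been turned into date numbers, and 44 lines share a symbol with another line. These do not belong to any list used here.

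The ratio of each gene was computed as TRPM2-KD over Control. The size of a difference was taken on log2(RPKM + 1), a scale that understates the difference of genes with low RPKM, among the 13988 genes with a mean RPKM of 1 or more over the 2 libraries. Genes at least 2-fold higher or lower on that scale were counted. The ratio given for a named gene is the plain ratio of RPKM, without the added 1. Its interval is the exact conditional binomial (Clopper-Pearson) 95% interval of the read counts. Such an interval covers counting error only, and reads are not independent molecules when made by PCR. With 1 library per group there is no replicate check, no test of the conditions and no p-value of this re-analysis, and the difference between the conditions cannot be separated from the difference between 1 pair of libraries. The counts of genes past 2-fold were set against 100 simulated pairs of libraries in which each gene's reads were split at the ratio of the library totals.

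Before the data were examined, 41 gene lists were fixed. The median log2 ratio of the measured members of each list was placed among the medians of 10000 random lists of the same size, drawn with replacement from genes in the same of 20 bins of mean expression. A list was said to stand apart below the 2.5th or above the 97.5th percentile. By chance about 5% of lists of independent genes do so. The lists share some genes, and members of a list can vary together, which can make standing apart more frequent. The counting interval of a median comes from 1000 resamplings of the counts with Poisson error. Gene ontology terms listed in the table with 15 to 300 measured members were treated in the same way. The percentiles describe these libraries and are no test of the conditions. Members were matched by symbol and otherwise by gene identifier. After the data were seen, 3 further lists were written, of other myeloid genes, of abundant macrophage genes and of neutrophil genes.

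Genes were named by rules fixed before the data were examined. They are Trpm2 and the TRP channel genes past the filter, the 12 highest and 12 lowest ratios among genes with a mean RPKM of 3 or more and 50 or more reads, up to 4 members of each list with the largest absolute log2 ratio, a fixed set of Wnt, progenitor, neuronal, heat and cold response and reference genes, and the 5 largest gains and 5 largest losses in RPKM. In the ranking by ratio, RIKEN, Gm and LOC models, pseudogenes by their symbol (-ps), microRNAs, snoRNAs and entries without a symbol, counting clone names and date numbers as such, were left out. Any gene named outside these rules is marked as chosen after its values were seen. Some genes that the rules take are not reported here.

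The reference annotation used here, GENCODE M21, belongs to a later build than mm9. It served for gene types and for the GC content of transcripts, with 15919 identifiers (98.9%) matched without their version, and no genome positions are given. Gene length was taken from the deposited counts and RPKM together.

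The alternatives tried were a pseudocount of 0.1 or 0.5, no filter, a filter at a mean RPKM of 5, median-ratio and TMM (trimmed mean of M values) scaling, CPM in place of RPKM, genes whose counting interval lies wholly beyond 2-fold, random lists matched also on gene length in 10 bins of each property, and lists without members shared with other lists. Random lists matched on length and GC content, in 5 bins of each property, and random lists drawn from genes outside the list, were added after the data were seen. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated counts for the 13988 genes of TRPM2-KD over Control, with 200 genes changed. The 2-fold rule found 100% of genes raised 3-fold, 86% of genes lowered 3-fold, 100% of genes raised 6-fold and 98% of genes lowered 6-fold, and it called 0 unchanged genes. The counting intervals held the true ratio for 95.6% of genes. Of 400 lists without a shift 3.75% stood apart, and of 100 lists of 25 genes shifted by 0.2 on the log2 scale 96% did. Members of these simulated lists were drawn at random. The rates therefore do not cover real lists, whose members can vary together between any pair of libraries.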

Results

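The transcriptome of GFP-positive cortical progenitors was sequenced after in utero electroporation with a Trpm2 knockdown or a control plasmid. TRPM2 is a calcium-permeable cation channel that opens in response to warmth and oxidative signals. There was 1 library per group, with 26209192 counted reads in Control and 20791236 in TRPM2-KD, so no difference below has a replicate check and every interval covers counting error only. Genes encoded by the mitochondrial genome held 3.08% of the reads in Control and 3.12% in TRPM2-KD, and the 10 most abundant genes held 3.83% and 3.93%.

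Trpm2 itself was lower in the library labelled TRPM2-KD, by a small margin. It (ENSMUSG00000009292.11) had 241 reads in Control and 155 in TRPM2-KD, or 0.745 and 0.604 RPKM. The ratio was 0.811, with a counting interval from 0.658 to 0.996 that ends just short of 1. At this level Trpm2 lies below the expression filter used for the gene lists. The authors' deposited table gives it a log2 fold change of -0.30 and a p-value of 0.657. Of the other TRP channel genes, 11 were measured. Trpm7, a channel fused to a kinase, was at a ratio of 1.29 (1.23 to 1.36) and Trpc1 at 1.37 (1.09 to 1.71). Trpm4, a calcium-activated channel, was at 0.691 (0.60 to 0.794), and Trpc4 was at 0.722. The median log2 ratio of the 11 genes was 0.003, within the random lists at percentile 44.3, with 6 members above 0 and 5 below.

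Most genes were at similar levels in both libraries. Of 13988 genes, 13097 (93.6%) lay within 1.5-fold, and across genes, which are not independent replicates, the Pearson correlation of log2(RPKM + 1) was 0.975 and the Spearman correlation was 0.973. There were 128 genes at least 2-fold higher in TRPM2-KD and 96 genes at least 2-fold lower in TRPM2-KD. Counting error alone gave on average 0.63 and 1.04 such genes. Protein-coding genes made up 49 of the 128 and 32 of the 96. Many were short or thinly covered. Of all 128 genes 96 were under 1 kb and 52 had fewer than 50 reads over both libraries, and of all 96 genes 78 and 36. With a minimum mean RPKM of 5 the numbers were 49 and 38, and with a pseudocount of 0.1 they were 296 and 209.

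Several genes known from immune cells were among the 12 highest ratios. P2ry6, a nucleotide receptor of microglia, was at a ratio of 4.32 (3.21 to 5.87), with 59 reads in Control and 202 in TRPM2-KD. Pik3ap1, a signalling adaptor of immune cells, was at 3.68 (2.98 to 4.56). The chemokine gene Ccl5 was at 2.95, the formyl peptide receptor gene Fpr2 at 3.15, S100a9, a neutrophil calcium-binding protein, at 2.31, and the leukocyte surface antigen gene Cd52 at 2.52. Also high were Styx at 4.49, Crip1 at 2.96, Znhit3 at 2.63 and the entry Lars2, a mitochondrial leucyl-tRNA synthetase gene, at 2.93 (2.84 to 3.02). Whether the reads counted for Lars2 come from ribosomal RNA was not tested, so they are uncertain. Tsix, which lies antisense to Xist, was at 2.55, but without known strand its reads cannot be told from those of Xist. The largest ratio under the naming rule was that of the globin gene Hbb-bt, with 3 reads in Control and 166 in TRPM2-KD, or 69.7 (23.5 to 342). Hbb-bt is a near copy of Hbb-bs, so its reads are uncertain.

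The 12 lowest ratios belonged to genes of several kinds. Pglyrp1, a peptidoglycan-binding protein of neutrophils, went the other way from S100a9, with 235 reads in Control and 44 in TRPM2-KD and a ratio of 0.236 (0.167 to 0.327). The neuropeptide genes Gnrh1, Cort and Avp were at 0.272 (0.141 to 0.489), 0.369 (0.235 to 0.563) and 0.403 (0.272 to 0.584). Tmem107, a protein of the ciliary transition zone, was at 0.378 (0.301 to 0.472) and Fam183b at 0.400. Fabp3, a fatty acid carrier, was at 0.427 and Phpt1 at 0.405. Zfp125, which the annotation types as a transcribed pseudogene and whose symbol does not mark it as one, was at 0.399. The histone genes Hist1h4b and Hist1h4a were at 0.201 and 0.315, and the entry adapt33_1 was at 0.229, all 3 with 15 reads or fewer in TRPM2-KD. The largest gains in RPKM were those of Gm23935 (ratio 2.97), Gm26924 (2.61), Gm24270 (2.23), Gm24187 (2.87) and mt-Tp (1.84), and the largest losses those of mt-Co3 (0.947), mt-Co2 (0.935), Gm23134 (0.709), Nnat (0.820) and H19_1 (0.761). Whether the reads of these Gm models come from ribosomal RNA was not tested either, so their gains are uncertain.

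By the rule stated for the series, a p-value under 0.05 and an absolute log2 fold change over 1, the authors' deposited table holds 348 genes higher and 270 lower in TRPM2-KD. That comparison is between the 2 libraries, not between the conditions. Of these 618 genes, 218 had a mean RPKM of 1 or more, and the median gene had 48 reads over both libraries. The adjusted p-value in the authors' deposited table is under 0.05 for 100 genes, 53 higher and 47 lower, and 51 of the 100 had 0 reads in 1 of the libraries.

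Of the 41 gene lists, 15 stood apart from random lists of matched expression, 8 higher and 7 lower in TRPM2-KD. By chance 2.05 are expected if genes vary independently, which members of a list need not do. The ratio also followed gene length. With the genes split by length into 10 equal groups, the median log2 ratio was -0.06 in the shortest group and 0.08 in the longest, and across genes the Spearman correlation of the ratio was 0.155 with length and -0.20 with GC content. With random lists matched also on length, 14 of the 15 stood apart on the same side.

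**Figure D1:**
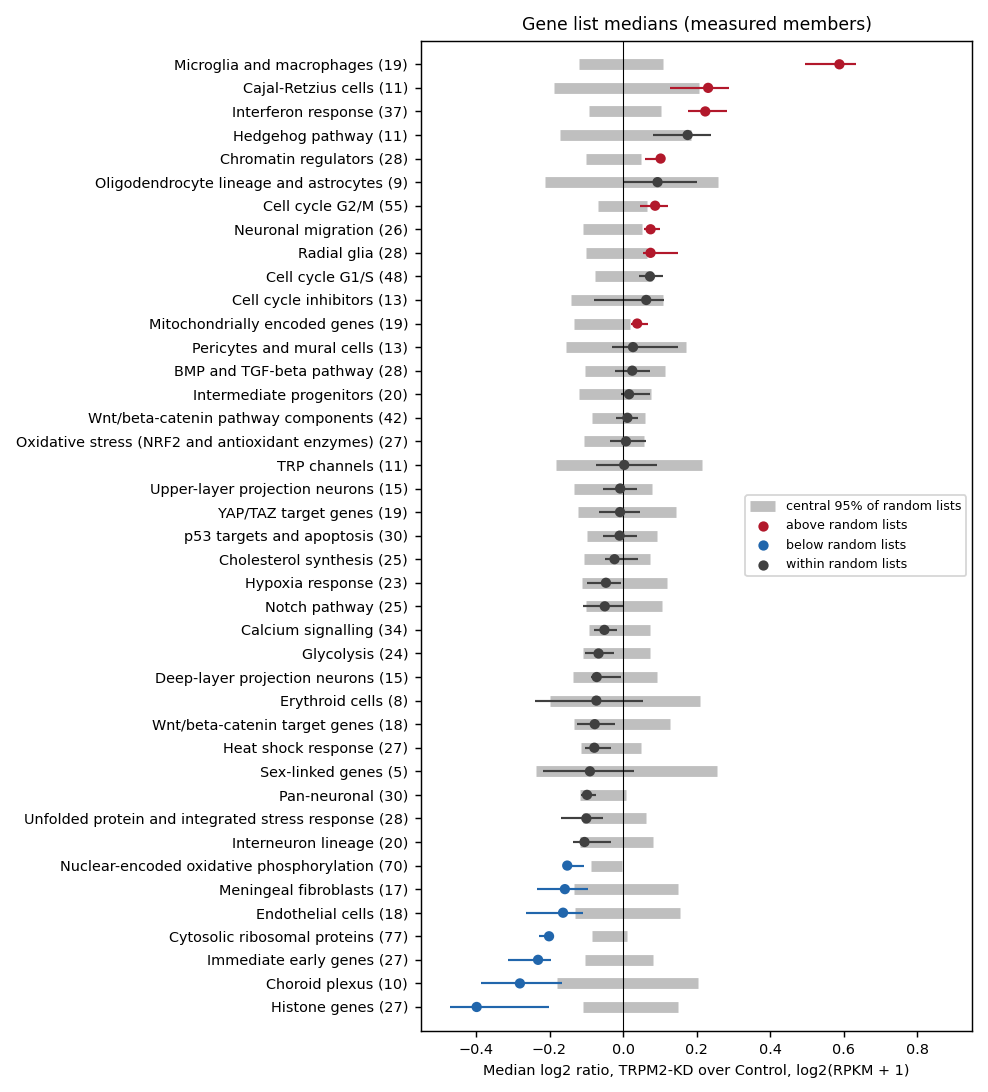
Median log2 ratio of TRPM2-KD over Control for each of the 41 gene lists, on log2(RPKM + 1), with the number of measured members in parentheses. Points are medians, thin lines their 95% counting intervals and grey bars the central 95% of 10000 random lists of matched expression. Microglia and macrophage genes lie farthest to the right at 0.59 and histone genes farthest to the left at -0.40.

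The series asks about TRPM2 and beta-catenin, so Wnt signalling genes were examined. Neither fixed Wnt list stood apart. The beta-catenin gene Ctnnb1 was at a ratio of 0.955 (0.939 to 0.972). Its target genes went both ways. Axin2, a negative feedback regulator of the pathway, was higher in TRPM2-KD at 1.53 (1.39 to 1.69), as was Nkd2 at 1.5 (1.26 to 1.78). Myc was lower at 0.633 (0.556 to 0.719), Lef1 at 0.797 (0.702 to 0.905), Sp8 at 0.813 (0.722 to 0.915) and Ccnd1, the G1 cyclin, at 0.889 (0.825 to 0.957). For Sp5, a transcription factor induced by Wnt signalling, the ratio was 1.2 with an interval from 0.909 to 1.59 (108 and 103 reads), so no difference was detectable at this depth. Of the 18 measured targets 8 were above 0 and 10 below, the counting intervals of 4 lay above 1 and of 9 below, and the median log2 ratio was -0.08 (percentile 12.7). Of 42 pathway components 22 were above 0 and 20 below, with a median of 0.01 (percentile 75.5). Among them the receptor genes Fzd10 and Fzd3 were at 2.0 (1.59 to 2.53) and 1.35 (1.24 to 1.46), Lgr4 at 1.34 and Wnt5a at 1.29. Of the gene ontology terms on this pathway, picked out after their values were seen, Wnt signaling pathway (113 genes) had a median of 0.04 at percentile 98.2, and 97.0 with length matched or 95.98 with GC content matched too. With expression alone matched, the term beta-catenin binding (54 genes) had a median of 0.09 at percentile 99.5. On the same matching, canonical Wnt signaling pathway (31 genes) had one of 0.08 at percentile 92.2. The term negative regulation of Wnt signaling pathway (20 genes) had a median of -0.06 at percentile 14.6, and Wnt-protein binding (24 genes) was at percentile 46.3, with 12 genes above 0 and 12 below.

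Radial glia genes as a list were slightly higher in TRPM2-KD. The median log2 ratio of the 28 genes was 0.07 (counting interval 0.05 to 0.15, percentile 98.4), with 20 above 0 and 8 below, and 13 counting intervals above 1 and 4 below. Tnc, an extracellular matrix protein, was at a ratio of 1.66 (1.57 to 1.76), the glutamate transporter gene Slc1a3 at 1.56 (1.47 to 1.65), the endothelin receptor gene Ednrb at 1.45 and Sox3 at 1.39. The core progenitor factors were near 1, with Pax6 at 1.00 (0.931 to 1.08) and Sox2 at 1.01 (0.968 to 1.06). The Notch effectors Hes1 at 0.942 and Hes5 at 0.936 had intervals that span 1. Genes of intermediate progenitors were evenly split, 10 above 0 and 10 below, with a median of 0.02 (percentile 77.2). Eomes was at 1.03 with an interval that spans 1, Neurog2 at 0.928 (0.878 to 0.981), Neurog1 at 0.660, Nhlh1 at 1.46, Abcd2 at 1.53 and Tac2 at 3.09 (1.98 to 4.93, 29 and 71 reads). With only the members found in no other list, the intermediate progenitors median was 0.17 and the list stood apart at percentile 99.6.

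Pan-neuronal genes were mostly slightly lower, 23 of 30, with a median log2 ratio of -0.10 (counting interval -0.12 to -0.07). The list did not stand apart by expression alone (percentile 7.33), but it did when length was matched as well (percentile 0.06). The cytoskeletal genes Mapt and Stmn2 were at ratios of 0.813 (0.799 to 0.827) and 0.839, Rbfox3 at 0.853 and Tubb3 at 0.915 (0.901 to 0.930). Dcx, a microtubule-binding protein of migrating neurons, was at 1.08 (1.06 to 1.09). The 15 deep-layer genes had a median of -0.07 (percentile 20.2), with Neurod2 at 0.907, Tbr1 at 0.861, Fezf2 at 0.795 and Crym at 1.38. The 15 upper-layer genes had a median of -0.01 (percentile 66.4), with Pou3f2 at 1.18 and Lmo4 at 0.842. Neuronal migration genes stood apart higher, with a median of 0.07 over 26 genes (percentile 99.5, 20 above 0) and Nrp2 at 1.18, Plxna4 at 1.16 and Ndel1 at 0.752, but within the random lists when length was matched (percentile 95.8). Interneuron lineage genes had a median of -0.10 (percentile 4.08), with Dlx2 at 0.800, and among genes with a mean RPKM of 5 or more the interneuron lineage list stood apart (percentile 1.07).

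Of the 3 cell cycle lists only the G2/M list stood apart, slightly higher in TRPM2-KD. Cell cycle G2/M genes had a median log2 ratio of 0.09 over 55 genes (counting interval 0.05 to 0.12, percentile 99.5), with 35 above 0 and 20 below, but the percentile was 95.7 among genes with a mean RPKM of 5 or more. The genes with the largest ratios went both ways, with the cytokinesis gene Anln at 1.5 (1.32 to 1.71), the centromere histone gene Cenpa at 0.642 (0.576 to 0.715), Birc5 at 0.625 and Cdca3 at 0.726. The proliferation marker Mki67 was at 1.19 (1.14 to 1.24). Cell cycle G1/S genes, with Cdk6 at 1.58 and Cdc6 at 1.68, had a median of 0.07 over 48 genes (percentile 96.7), and they stood apart with length matched (percentile 98.5). With GC content matched too, the G1/S genes lay within the random lists (percentile 95.85). The 13 cell cycle inhibitors had a median of 0.06 (percentile 88.6), with Rbl2 at 1.32 and Gadd45a at 0.776. The gene ontology term cell division (280 genes), picked out after its value was seen, had a median of -0.004 at percentile 50.95.

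**Figure D2:**
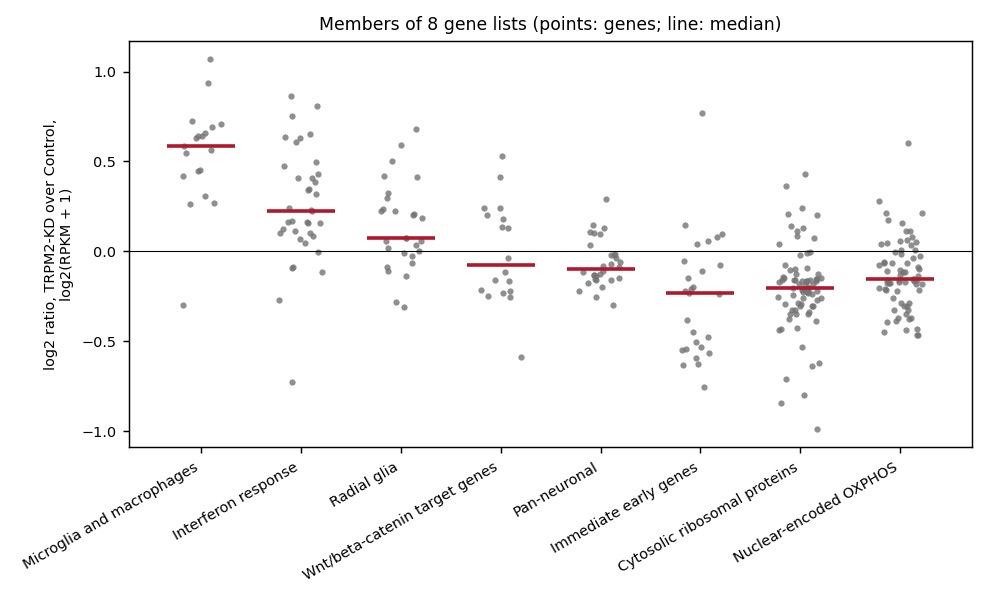
Log2 ratio of TRPM2-KD over Control, on log2(RPKM + 1), of each measured member of 8 gene lists. Each point is a gene and each red line the median of its list. Of the microglia and macrophage genes 18 of 19 lie above 0, and of the ribosomal protein genes 66 of 77 lie below 0.

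Immediate early genes, which respond within minutes to stimulation, were lower in TRPM2-KD. Of 27 genes 21 were below 0, with 18 counting intervals below 1 and 1 above, and the median log2 ratio was -0.23 (counting interval -0.31 to -0.20), below all 10000 random lists. Egr1 was at a ratio of 0.589 (0.567 to 0.611), with 8717 reads in Control and 4071 in TRPM2-KD, Dusp1 at 0.637 (0.598 to 0.679) and Nr4a1 at 0.614 (0.534 to 0.703). Zfp36, which speeds the decay of inflammatory mRNAs, was the 1 member with a counting interval above 1, at 1.77 (1.58 to 1.98). Heat shock genes did not stand apart, with a median of -0.08 over 27 genes (percentile 14.2), 17 of them below 0. The small heat shock genes Hspb1, Hspb8 and Cryab were at 0.461 (0.237 to 0.851), 0.617 (0.459 to 0.824) and 0.598 (0.367 to 0.953), and the co-chaperone gene Bag3 at 1.80 (1.30 to 2.5). Hspa1b, a heat-inducible chaperone gene with a near copy in Hspa1a, had 58 and 21 reads and a ratio of 0.456 (0.263 to 0.763). Hspa1a was not analysed here. The cold-inducible genes Cirbp and Rbm3 were at 0.888 (0.859 to 0.917) and 1.04 (0.990 to 1.08).

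Other stress lists did not stand apart. The list of the unfolded protein and integrated stress responses had a median of -0.10 over 28 genes (percentile 4.04), 20 of them below 0, with Eif4ebp1 at a ratio of 0.611, Atf3 at 0.599, Sesn2 at 0.624 and Dnajb9 at 0.681. Antioxidant genes had a median of 0.01 (percentile 81.9) but a mean of -0.03. The metallothionein gene Mt1 was at 0.505 (0.414 to 0.613), Gpx4 at 0.773, Srxn1 at 1.59 and Cat at 1.37. Genes of p53 and apoptosis had a median of -0.01 (percentile 45.0), with Perp at 0.353 and Phlda3 at 0.509. Hypoxia genes had a median of -0.05 (percentile 18.4), with Ak4 at 1.31. Glycolysis genes had a median of -0.07 (percentile 14.6), with Ldhb at 0.843 and Slc2a3 at 1.21. Gapdh had only 386 and 375 reads, with a ratio of 1.22, and has many pseudogenes, so its reads are uncertain. The reference gene Actb was at 0.990 (0.980 to 1.001).

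Genes of microglia and macrophages were higher in TRPM2-KD, and so were interferon response genes. Of 19 microglia and macrophage genes 18 were above 0, and 17 counting intervals lay above 1. The median log2 ratio was 0.59 (counting interval 0.50 to 0.63), or 1.5-fold, above all 10000 random lists. Aif1 was at a ratio of 2.29 (1.94 to 2.70), the signalling adaptor gene Tyrobp at 1.97 (1.67 to 2.34), the protease gene Ctss at 1.68 and the purine receptor gene P2ry12 at 2.73 (1.82 to 4.17). Of the 37 interferon response genes 31 were above 0, with 23 counting intervals above 1 and 2 below, and a median of 0.22 (counting interval 0.18 to 0.28), also above all random lists. The antiviral gene Oasl1 was at 2.78 (2.02 to 3.86) and Gbp2 at 2.30. Mx2, which the annotation types as a polymorphic pseudogene, was at 1.94 (1.60 to 2.37). The chemokine gene Cxcl10 was lower at 0.398 (0.240 to 0.637).

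Markers of endothelial cells, meninges and choroid plexus were lower in TRPM2-KD. Endothelial genes had a median of -0.16 over 18 genes (percentile 0.84), 13 of them below 0, with Mfsd2a at a ratio of 0.633, Ly6c1 at 0.587, Sox18 at 0.647 and Slco1c1 at 1.41. Meningeal fibroblast genes had a median of -0.16 over 17 genes (percentile 1.27), 14 below 0, with Col1a1 at 0.615 (0.582 to 0.650), Foxd1 at 0.384 and Dcn at 0.732. Among genes with a mean RPKM of 5 or more the list of meningeal fibroblasts did not stand apart (median -0.105, percentile 11.9). Choroid plexus genes had a median of -0.28 over 10 genes (percentile 0.24), 7 below 0, with Ttr at 0.701 (0.681 to 0.722) and Aqp1 at 0.558, but without an expression filter the choroid plexus median was -0.118 (percentile 8.42). Mural cell genes had a median of 0.03 (percentile 57.1), with Higd1b at 0.447 and Tagln at 1.70. The 8 erythroid genes had a median of -0.07 (percentile 21.4) but a mean of 0.23, with Epor at 0.483 and Hbb-y at 0.630. Cajal-Retzius genes stood apart higher, with a median of 0.23 over 11 genes (percentile 98.5), 9 above 0, with Ndnf at 2.52 (2.01 to 3.17) and Ebf3 at 1.81 (1.64 to 1.99), while among genes with a mean RPKM of 5 or more the list of Cajal-Retzius cells was at percentile 97.2. The 9 oligodendrocyte and astrocyte genes had a median of 0.09 (percentile 71.5), with Gpr17 at 3.90, Olig1 at 1.60 and Sox10 at 0.445. The sex-linked list had a median of -0.09 (percentile 23.7). It joins Xist with genes of the Y chromosome, which would move in opposite directions with embryo sex, so its median cannot show such a difference. Xist was at 1.37 (1.35 to 1.39), Eif2s3y at 0.699, Uty at 0.696 and Ddx3y at 1.21. Whether the libraries differ in the sex of their embryos was not tested.

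The fixed lists of ribosomal protein and oxidative phosphorylation genes were lower in TRPM2-KD. Of 77 cytosolic ribosomal protein genes 66 were below 0, with 56 counting intervals below 1 and 8 above, and the median log2 ratio was -0.20 (counting interval -0.23 to -0.19), below all 10000 random lists. Rps6 was at a ratio of 0.436 (0.345 to 0.547), Rpl29 at 0.499, Rps2 at 0.560 and Rplp2 at 0.594, although these genes have many pseudogenes and their reads are uncertain. Of 70 nuclear genes of oxidative phosphorylation 53 were below 0, with 42 counting intervals below 1 and 7 above, and a median of -0.15 (counting interval -0.16 to -0.11). Uqcrq was at 0.725 (0.663 to 0.792), Atp5g1 at 0.637 and Ndufb2 at 1.85. These lists hold short genes, with median lengths of 1.47 and 1.34 kb, but with length matched the percentiles were 0 and 0.63. Gene ontology terms on the respiratory chain, picked out after their values were seen, did not stand apart with length matched. The term mitochondrial respiratory chain complex I went from percentile 0.71 to 23.45, and cytochrome-c oxidase activity from 5.96 to 38.4. The wider term mitochondrial inner membrane (292 genes), picked out in the same way, did stand apart with length matched. Its median was -0.08, at percentile 0 by expression and 0.28 with length matched. Histone genes had a median of -0.40 over 27 genes (percentile 0), with 8 above 0 and 19 below, 6 counting intervals above 1 and 13 below, and 3 genes at least 2-fold higher against 5 lower. Among the lowest, Hist1h2bl had 30 and 1 reads, Hist1h2bg 37 and 0 and Hist2h2aa2 29 and 0. With a minimum mean RPKM of 5 the median of the histone genes was -0.12 (percentile 8.77).

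**Figure D3:**
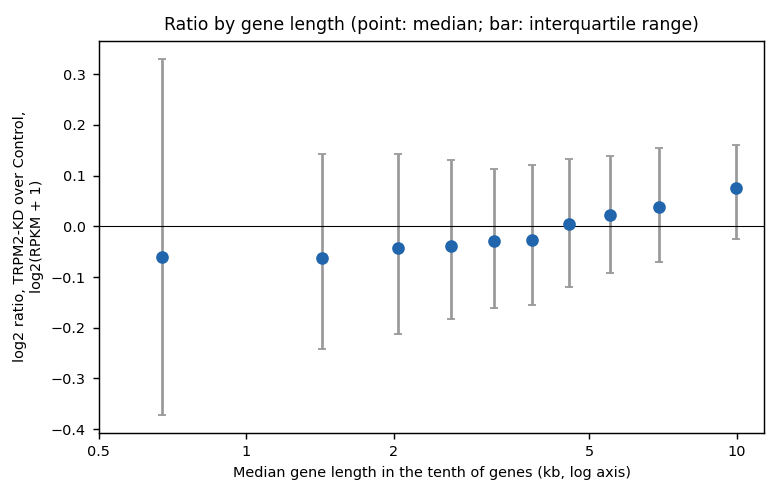
Log2 ratio of TRPM2-KD over Control, on log2(RPKM + 1), for the 13988 genes split by gene length into 10 equal groups, against the median length of each group in kb on a log axis. Points are medians and bars interquartile ranges. Medians go from -0.06 in the shortest group, at 0.673 kb, to 0.08 in the longest, at 9.95 kb.

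Chromatin regulators, which are long genes with a median of 7.41 kb, stood apart higher with a median log2 ratio of 0.10 over 28 genes (percentile 99.96, and 98.5 with length matched). Kmt2a was at a ratio of 1.21 (1.17 to 1.25), Suz12 at 1.19, Rad21 at 1.15 and Hdac3 at 0.834. The 19 genes encoded by the mitochondrial genome had a median of 0.04 (percentile 99.0) but a mean of -0.04, and mt-Tw had 47 and 2 reads. With random lists matched on length and GC content, chosen after the data were seen, the mitochondrially encoded genes were within them (percentile 89.5). Among other signalling lists, none stood apart. Hedgehog genes had a median of 0.18 over 11 genes (percentile 96.9, and 98.5 with length matched), with Gas1 at 1.52 (1.38 to 1.67), Gli2 at 1.37 and Gli1 at 0.793. Notch genes had a median of -0.05 (percentile 16.4), with the ligand gene Dll4 at 0.606 (0.503 to 0.728) and Rbpj at 0.790. Genes of BMP and TGF-beta had a median of 0.02 (percentile 63.2) but a mean of -0.03, with Id1 at 0.621 and Bmpr2 at 1.52. YAP/TAZ targets had a median of -0.01 (percentile 38.6), with F3 at 0.661. Calcium signalling genes had a median of -0.05 (percentile 16.2, and 1.44 with length matched), with the store-operated channel gene Orai1 at 0.632 (0.519 to 0.768) and Ppp3ca at 0.803. Cholesterol synthesis genes had a median of -0.02 (percentile 45.8) but a mean of 0.03, with Hmgcs1 at 1.19.

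Of 1141 gene ontology terms, 125 stood apart, 85 higher and 40 lower. By chance 57.05 are expected if genes vary independently, and terms share genes. The lowest medians were those of ribosomal large subunit biogenesis (-0.30), response to cAMP (-0.20), mitochondrial ribosome (-0.20), cellular response to hormone stimulus (-0.19) and ribosomal small subunit assembly (-0.19). With length matched the last of these was within the random lists at percentile 2.67. The highest medians were those of cellular response to interferon-beta (0.25), midbrain development (0.23), podosome (0.18), defense response to Gram-positive bacterium (0.17) and protein destabilization (0.17).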

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

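Random lists matched on length and GC content, and those drawn from genes outside the list, were chosen after the data were seen. No list that stood apart, and no named gene with a counting interval off 1, changed its direction under the alternatives run. No paired analysis was possible because each group holds 1 library, and for the same reason no library could be left out. Trpm2 stayed at a ratio of 0.811 to 0.813 under the other scalings and CPM, and the scaling factors were 0.997 and 0.9995. The 128 genes at least 2-fold higher in TRPM2-KD became 49 and the 96 genes at least 2-fold lower in TRPM2-KD became 38 at a mean RPKM of 5 or more, where fewer genes enter. With a pseudocount of 0.1 they were 296 and 209, and with 0.5 there were 198 higher, since a smaller pseudocount shrinks low genes less. Genes whose counting interval lies wholly beyond 2-fold numbered 107 and 67.

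At a mean RPKM of 5 or more, 5 lists crossed the percentile limits and lists with under 5 members gave no value. Cell cycle G2/M genes then had a median of 0.059 (percentile 95.7), Cajal-Retzius cells one of 0.231 (97.2) and meningeal fibroblasts one of -0.105 (11.9). Histone genes had a median of -0.12 (8.77) and the interneuron lineage one of -0.136 (1.07). Choroid plexus genes had a median of -0.118 without a filter (8.42). Cell cycle G1/S genes stood apart without a filter (0.0859, percentile 98.8), and also with a pseudocount of 0.1 (0.0929), with CPM (0.0902) and with length matched (0.0732, from all genes or from outside the list). With length and GC content matched the G1/S genes did not (percentile 95.85). Intermediate progenitors stood apart without shared members (0.169, percentile 99.6). Matching changes only the percentile. With length matched, alone or with GC content, from all genes or from outside the list, calcium signalling (-0.0507), Hedgehog pathway (0.176) and pan-neuronal genes (-0.0981) stood apart, and neuronal migration (0.0748) did not. With length and GC content matched, mitochondrially encoded genes (0.0384) no longer stood apart. The cause of these changes was not tested beyond the matching itself. Of the other comparisons, 498 of list medians, 42 of counts and 1062 of named genes were the same, and 38 values of named genes moved beyond their counting interval, mostly with a pseudocount of 0.1 or CPM. Depth limits the statements on genes with few reads, such as Trpm2 and Sp5.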

Other observations

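The lists of other myeloid, abundant macrophage and neutrophil genes, and the tests on non-neural markers and on globin genes, were chosen after the results were seen.

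Myeloid genes outside the fixed lists were also mostly higher in TRPM2-KD. Of 44 other myeloid genes, none of them in a fixed list, 38 were above 0 and 31 had counting intervals above 1. Of these genes, Cd52 had already been seen among the 12 highest ratios. In the same list Spi1, Ccl4 and Cd37, chosen after their values were seen, were at ratios of 0.920, 0.557 and 0.671. The 13 measured neutrophil genes had a median log2 ratio of 0.27 (percentile 99.8), with 8 above 0 and 5 below, and that list includes S100a9 and Pglyrp1, already seen among the highest and the lowest ratios.

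Microglia and macrophage genes had a median log2 ratio of 0.588 in TRPM2-KD over Control. A trend with gene length and GC content is argued against, since the list lay at percentile 100 of lists matched on both. A lower share of neural cells as the sole cause would raise the markers of all other cell types alike. The 48 endothelial, mural and meningeal markers argue against that, although the medians of their lists had already been seen. Their median was -0.113 (bootstrap 95% interval over genes -0.225 to -0.0451, against 0.448 to 0.656 for the myeloid genes). These intervals cover the spread over genes in this pair of libraries, not between libraries. More myeloid RNA in the TRPM2-KD library remains a candidate explanation that cannot be told apart from a changed state of such cells: the other myeloid genes had a median of 0.288, just under the 0.3 set beforehand and above all random lists, and 15 abundant macrophage genes, 3 of them also in fixed lists and many also expressed by neural cells, had one of 0.0475, at percentile 98.7 with 12 above 0. The GFP sort is meant to remove myeloid cells, but the Control library also held reads of such genes. Tyrobp had 230 reads there (15.5 RPKM) and Ctss 814 (22.8 RPKM), so the sort does not speak against myeloid RNA. An effect of the knockdown stays open because it coincides with the library.

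Cytosolic ribosomal protein genes and nuclear oxidative phosphorylation genes were lower in TRPM2-KD. The trend with length as the whole cause is argued against, since against length-matched lists from outside each list they lay at percentiles 0 and 0.42, and with GC content matched too at 0 and 0.07. For oxidative phosphorylation this holds for the fixed list, while with length matched the gene ontology terms mitochondrial respiratory chain complex I (percentile 23.45), NADH dehydrogenase (ubiquinone) activity (35.1), cytochrome-c oxidase activity (38.4), mitochondrial proton-transporting ATP synthase complex (47.3) and ATP synthesis coupled proton transport (40.2) lay within the random lists, so part of the difference may follow length. The wider term mitochondrial inner membrane (292 genes) still stood apart lower, at percentile 0.28 with length matched and 0.15 with GC content matched too. The 21 ribosomal genes at a mean RPKM of 100 or more had a median of -0.222, where random lists gave -0.130 to 0.0047 (percentile 0). Reads shared with pseudogenes had been taken beforehand to predict a median within those lists. The lower values are thus not confined to ribosomal genes with few reads. The share of reads lost to copies was not measured, even for these 21 genes, so reads shared with pseudogenes stay open. Other differences between the libraries and an effect of the knockdown stay open and were not tested.

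Hbb-bt had 3 reads in Control and 166 in TRPM2-KD. More erythroid RNA in the TRPM2-KD library is argued against, since the summed RPKM of Hbb-bs, Hbb-y, Hba-a1 and Hba-a2 was 1.035 times that of Control, and the ratio of their summed reads was 1.045 (0.970 to 1.13). A different beta-globin haplotype among the outbred embryos of each library, or a different split of reads with its near copy Hbb-bs, could give such a ratio, and neither was tested. An effect of the knockdown also stays open.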
